A study of Homo sapiens with 6 samples.

How the data were processed

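RNA was measured in 6 libraries of 22RV1 cells, 3 transfected with a control plasmid and 3 with a PLEK2 plasmid, made from 150 ng of RNA with a stranded mRNA kit, per the labels. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, adapters were trimmed with cutadapt and reads were aligned with STAR to GRCh38 (hg38). Versions, the read counter, its strand setting and the annotation release are not given in the sources used here. The deposited values are a signal per gene, read counts that the authors divided by 1 factor per library, per the file headers and the name of the deposited table, which calls them DESeq normalized counts. Coordinates are those of the deposited table. Of its 58395 rows, 99.8% had an identifier in GENCODE release 29, and 98.6% of the matched rows had the same location there. In 27 rows the gene symbol is written as a date, and those symbols were not repaired. No other column of per-sample values was present or used.

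In each library every non-zero value was a whole multiple of the smallest, to within 0.001 of a read, for 100% of values, so whole reads were recovered. The factors equal the size factors that DESeq2 computes from these reads, with a ratio of 1. Depth was 30348522 to 42784952 reads per library. For a gene of a few reads counting error is large, as for CSH2 with 31 reads over the 3 control libraries, and PCR duplicates are not told apart. Because the deposited values are normalized, the main test was limma (lmFit and eBayes with trend and robust) on log2(normalized count + 1), for the 21374 genes with a mean of at least 10 normalized counts over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are differences of group means on the log2(normalized count + 1) scale. The added 1 shrinks the change of low genes. A mean of logs lies below the log of the mean where libraries of a group differ. In the control group this can enlarge a rise, as for HSPA6 (5.36, against 5.20 by edgeR). As an alternative, edgeR's quasi-likelihood test with TMM factors on the recovered reads called 46 genes, 42 of them among the 42 of limma. DESeq2 on the same reads called 65, 41 of them shared, and gave no adjusted p for 6630 genes. The common biological coefficient of variation by edgeR was 6.46%.

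Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 29 lists with at least 5 measured members. The list of PLEK2 and the pleckstrin family also had that many members, but it was left out of camera by design. Counts of members that passed are given over all genes and adjusted over the list alone. The 33 lists were fixed before the data were examined, as were the design, the thresholds and the alternatives, except the removal of the GC and length trend, which was chosen after seeing the data. Of these, 1 is not reported here, though it is included in the counts of lists. The other 32 are androgen receptor targets, prostate luminal epithelium, basal and squamous epithelium, mesenchymal and EMT genes, metalloproteases and invasion, actin cytoskeleton and SRF targets, FOXO targets repressed by PI3K-AKT, PI3K-AKT-mTOR components, ERK and EGFR feedback targets, immediate early genes, type I interferon response, NF-kB and inflammatory cytokines, p53 targets, unfolded protein response and ATF4, heat shock response, G1/S and DNA replication, G2/M and mitosis, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, TGF-beta targets, WNT/beta-catenin targets, YAP/TAZ targets, neuroendocrine differentiation, fibroblast markers, leukocyte and red-cell markers, endothelial markers, and PLEK2 and the pleckstrin family. Lists share members, so their results are not independent.

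The genes named in the text were chosen by a rule: PLEK2, the 10 largest rises and up to 10 largest falls among genes past the threshold with a mean of at least 50 normalized counts, a gene symbol that is not a clone or locus name and no overlap between the groups, and from each list the 4 members with the smallest p-value. The rule named 5 falls because no more passed. Genes named outside it, such as SCDP1, HSPA7 and those of the growth hormone cluster, were chosen after their values were seen.

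The alternatives were pseudocounts of 0.5 and 5, no filter and a filter at a mean of 50, TMM and quantile normalization, eBayes without trend or robust, the replicate number as a block, each library left out in turn, the count tests above, and for lists an estimated correlation, fry and edgeR log CPM. For the GC and length trend, a lowess curve with a span of 0.3 was removed in each library, with values for 99.9% of tested genes. On data simulated for this comparison from the real means and library sizes, over 21374 genes of which 200 were changed, the test recovered 34% of genes changed by 0.25 on the log2 scale, 76% at 0.5, 96% at 1 and 100% at 2, and 2.55% of its 157 calls were false. The changed genes were drawn only from those with a mean of at least 50 normalized counts, so recovery of lower genes was not measured. Counts were drawn for each gene separately, without shifts that genes of a library share. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and Python 3.11.15.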

Results

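Messenger RNA was sequenced from 22RV1 cells, a human prostate cancer cell line that expresses the androgen receptor. The cells had been transfected with a plasmid for PLEK2 or with a control plasmid and were collected 48 hours later. PLEK2, pleckstrin-2, is a membrane-binding protein that acts on the actin cytoskeleton. Each group held 3 libraries, read as single reads of 50 bases. The whole reads recovered from the deposited values came to 30348522, 33130771 and 30814429 in control libraries 1, 2 and 3, and to 30887298, 42784952 and 39559877 in PLEK2 libraries 1, 2 and 3. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

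The libraries were close to each other. Correlations of log2 values lay between 0.989 and 0.991 within groups and between 0.987 and 0.990 between groups. The first principal component held 25.8% of the variance and placed all control libraries below 0 and all PLEK2 libraries above 0. Control library 1 stood farthest out on it, at -34.8, against -11.0 and -8.52 for control libraries 2 and 3. PLEK2 libraries 1, 2 and 3 stood at 27.7, 9.67 and 16.9. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per gene of 2.97 for control libraries 2 and 3, and of 10.4 and 9.47 for the pairs of control library 1 with control libraries 2 and 3. The pairs of PLEK2 libraries gave 4.78, 3.90 and 4.58.

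The comparison asked which transcripts differed after forced expression of PLEK2. PLEK2 itself (ENSG00000100558, GRCh38 chromosome 14, 67386983 to 67412200, minus strand) had 157.0, 134.5 and 138.9 normalized counts in the control libraries and 697874, 550235 and 554245 in the PLEK2 libraries. Its log2 fold change was 12.02 with a standard error of 0.07 (n = 3 per group, limma with Benjamini-Hochberg adjustment, adjusted p = 6.7e-39). An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. PLEK2 took 1.74% ± 0.24 of all reads in the PLEK2 libraries (SD, n = 3) and 0.000425% ± 0.000040 in the control libraries (SD, n = 3). Of the 5 other measured members of the pleckstrin family list, 1 rose, PHLDA3, which is also a p53 target, with a log2 fold change of 0.48. The same 1 member passed when adjusted over the list alone, and the median of the 5 was -0.05. The list also holds genes named for a pleckstrin-homology-like domain, PHLDA3 among them. A rise of a close relative of PLEK2 is therefore not shown.

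Beyond PLEK2, the largest rises were those of CSH2, HSPA6, FOS, TNFRSF19 and EGR1. HSPA6, a heat-inducible chaperone (ENSG00000173110, chromosome 1, 161524540 to 161526910), rose from 9.49 ± 6.81 to 347.4 ± 27.0 normalized counts (SD, n = 3 per group). The size of this rise depends on control library 2, which had 2.1 normalized counts, the lowest of the 3 values. The log2 fold change was 5.36 with it and 4.63 without it. FOS, a subunit of the AP-1 transcription factor (ENSG00000170345, chromosome 14, 75278774 to 75282230), rose 2.93-fold, from 248.0 ± 10.8 to 729.7 ± 47.0 (SD, n = 3 per group). EGR1, a zinc finger transcription factor induced by growth factors (ENSG00000120738, chromosome 5, 138465490 to 138469315), rose 2.10-fold, from 1090.0 ± 86.8 to 2283 ± 73.5 (SD, n = 3 per group). TNFRSF19, a receptor of the tumour necrosis factor family (ENSG00000127863, chromosome 13, 23570370 to 23676104), rose 2.12-fold, from 47.0 ± 11.7 to 99.7 ± 17.5 (SD, n = 3 per group). CSH2, a placental hormone gene of the growth hormone cluster (ENSG00000213218, chromosome 17, 63872012 to 63873766), rose from 11.1 ± 3.87 to 3325 ± 366 (SD, n = 3 per group). Reads from the introduced construct counted as CSH2 remain a candidate explanation, so a rise of the cells' own CSH2 is not shown.

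In all, 42 of 21374 genes tested changed at an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment, 37 higher and 5 lower in the PLEK2 libraries. Of these, 6 rose at least 2-fold: PLEK2, CSH2 (log2 fold change 8.16 ± 0.18, SE), HSPA6 (5.36 ± 0.43), FOS (1.55 ± 0.10), TNFRSF19 (1.08 ± 0.23) and EGR1 (1.07 ± 0.07). The other 36 moved by less than 2-fold, and the median absolute log2 fold change of the 42 genes was 0.40. Further rises included HSPA1A (0.95), the kinase PLK2 (0.73), ATF3 (0.71) and JUN (0.66). The 5 genes that fell were MTCO2P22 (-0.64), C2orf48 (-0.40), CBLN2 (-0.34), GPR162 (-0.33) and DHRS2 (-0.30). MTCO2P22 lost its call without control library 1 (log2 fold change -0.49), without control library 3 (-0.65) and without PLEK2 library 1 (-0.65), 2 (-0.73) or 3 (-0.54), and also with a filter at a mean of 50 normalized counts, by quantile normalization and without trended and robust variance. The groups did not overlap in any of the 42 genes, and in 14.8% of all genes tested, where chance gives 10%. At an unadjusted p under 0.05, 965 genes were higher and 928 lower.

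**Figure D1:**
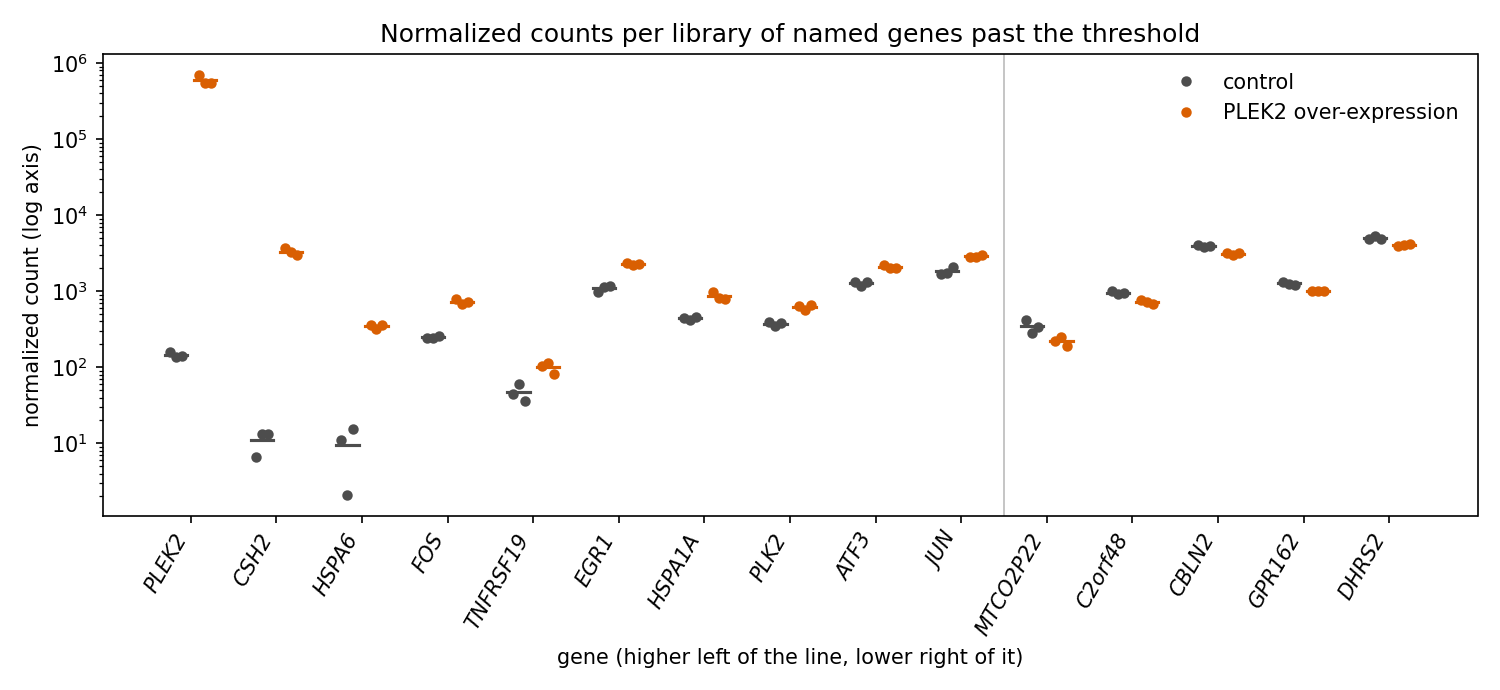
Normalized counts (log axis) of the 10 genes with the largest rise and the 5 that fell, 1 point per library and a bar at the mean of each group of 3. PLEK2 sits between 550235 and 697874 in the PLEK2 libraries and between 134.5 and 157.0 in the control libraries. The groups do not overlap for any gene drawn, which the rule that chose the genes required.

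Some of these genes share reads or positions with others. HSPA1A and HSPA1B are near-identical copies, and their summed normalized counts were 3361 ± 154 in control and 4366 ± 282 in PLEK2 libraries (SD, n = 3 per group), a log2 difference of 0.38, so the value of 0.95 for HSPA1A alone is uncertain. CSH2 belongs to a cluster of similar genes, HSPA6 has the near copy HSPA7, and MTCO2P22 and SCDP1 are pseudogene copies. Of the 42 genes, 7 overlap another tested gene, 3 of them on the same strand, among them C2orf48 and GPR162. Whether the counting used strand is not given in the sources used here.

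Immediate early genes, which answer growth factors and stress within minutes to hours, shifted upward as a group. Of 20 measured members, 5 rose (FOS, EGR1, ATF3, JUN and DUSP1), none fell and 15 did not pass. Adjusted over the list alone, 11 rose. The median log2 fold change was 0.32 (camera adjusted p = 1.6e-13), and the adjusted p was 0.095 with an estimated correlation. Of 24 targets of p53, genes of cell cycle arrest and apoptosis, 6 rose, among them GDF15 (0.62), PHLDA3 (0.48) and the cyclin-dependent kinase inhibitor CDKN1A (0.39), and 16 rose when adjusted over the list alone. Their median was 0.23 (camera adjusted p = 5.9e-13), with an adjusted p of 0.095 with an estimated correlation. Of 23 feedback targets of ERK and EGFR signalling, EGR1 and SPRED1 (0.29) rose, and 4 rose when adjusted over the list alone. The list's median was 0.19 (camera adjusted p = 6.6e-06), and the adjusted p was 0.096 with an estimated correlation.

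Further lists also shifted upward. Of 30 listed replication-dependent histones, 11 were measured in these libraries from a stranded mRNA kit. Whether the kit captured histone transcripts as a whole was not tested, so a rise of histone expression as a whole is not shown. Of the 11, 2 were higher, HIST1H2AC (0.60) and HIST2H2BE (0.47), and 3 when adjusted over the list alone. The median of the 11 was 0.24 (camera adjusted p = 0.0011, adjusted p = 0.15 with an estimated correlation). That median was 0.42 with no filter, 0.47 with a filter at a mean of 50 normalized counts and 0.38 without control library 3. Of 16 TGF-beta targets, ID1 (0.35) and ID2 (0.28) rose, 7 when adjusted over the list alone, with a median of 0.15 (camera adjusted p = 9.0e-06, adjusted p = 0.29 with an estimated correlation). Of 25 FOXO targets that PI3K-AKT represses, TXNIP (0.27) rose, 9 when adjusted over the list alone, with a median of 0.14 (camera adjusted p = 5.4e-05, adjusted p = 0.29 with an estimated correlation). The heat shock list, which does not hold HSPA6, had HSPA1A and HSPH1 (0.27) higher among 17 members, 6 when adjusted over the list alone, with a median of 0.06 (camera adjusted p = 0.00075, adjusted p = 0.44 with an estimated correlation). Without control library 1 the heat shock list did not pass (camera adjusted p = 0.078, range over its alternatives 8.4e-05 to 0.44), with a median of 0.04, against 0.11 without control library 2 and 0.12 without control library 3. In the cholesterol synthesis list HMGCS1 (0.27), an early enzyme of the pathway, was the 1 of 24 members that rose, 4 when adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.00053, adjusted p = 0.29 with an estimated correlation). None of the 18 YAP/TAZ targets passed over all genes and 3 passed when adjusted over the list alone, among them CTGF at 0.51, with a list median of 0.10 (camera adjusted p = 0.0015, adjusted p = 0.35 with an estimated correlation). That list did not pass without PLEK2 library 3 (camera adjusted p = 0.056, range over its alternatives 0.00040 to 0.35). Among 67 cytosolic ribosomal proteins RPL13 (0.31) rose, also when adjusted over the list alone, with a median of 0.03 (camera adjusted p = 0.042, adjusted p = 0.76 with an estimated correlation), and the list passed in 9 of 18 alternatives.

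Proliferation genes shifted the other way. All 30 measured genes of G2/M and mitosis had fold changes below 0 and none passed over all genes. When adjusted over the list alone, 5 fell, among them AURKB (-0.22) and CDK1 (-0.15). The list median was -0.10 (camera adjusted p = 2.0e-08, adjusted p = 0.31 with an estimated correlation). For G1/S and DNA replication, 27 of 30 were below 0, none passed over all genes, 5 fell when adjusted over the list alone, among them CDC45 (-0.18) and E2F1 (-0.16), and the median was -0.09 (camera adjusted p = 9.0e-06, adjusted p = 0.31 with an estimated correlation). Without control library 2 the G1/S median was -0.06 and the list kept its call.

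**Figure D2:**
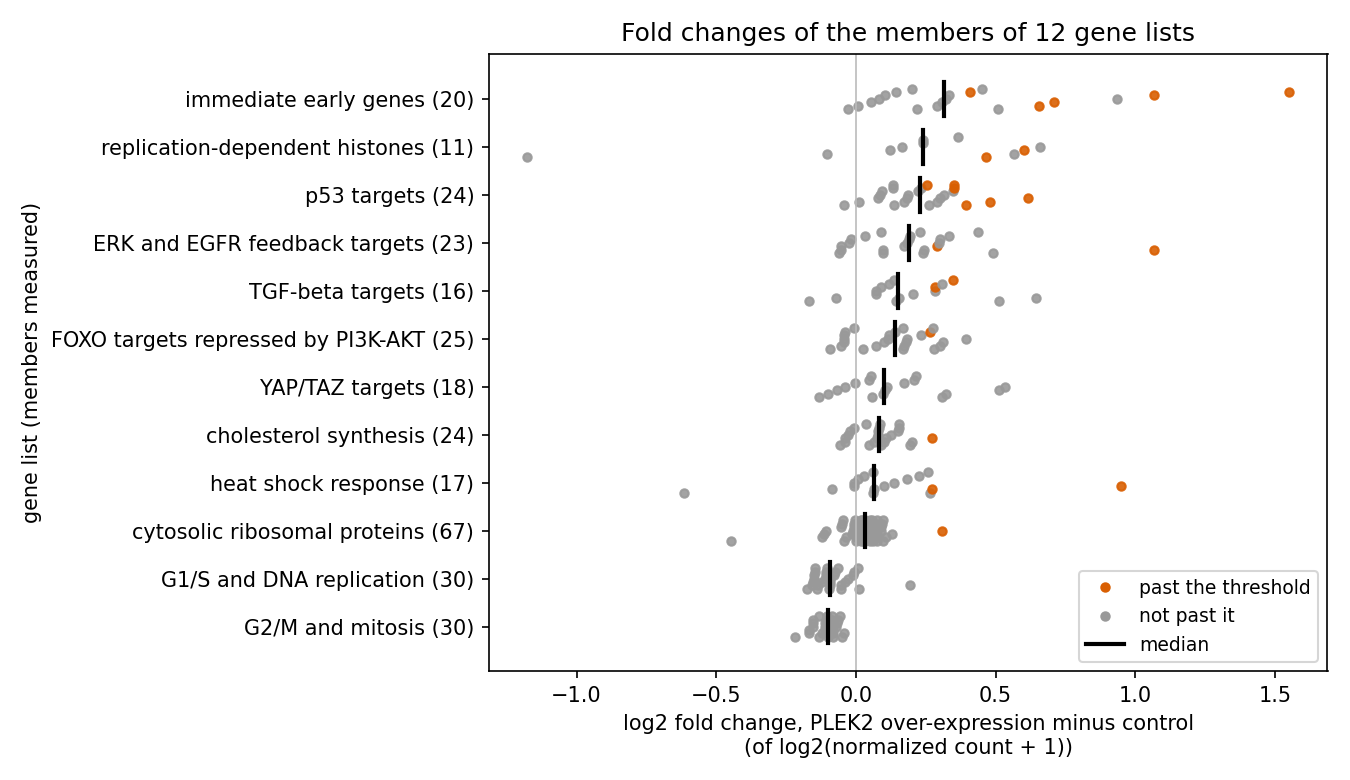
Log2 fold change of each measured member (points) of 12 gene lists past the threshold by camera, with the list median as a bar and genes past the threshold over all genes in orange. The median of the immediate early genes is 0.32 and that of G2/M and mitosis -0.10.

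The remaining 16 lists did not pass by camera, 3 of which passed under some alternative: oxidative phosphorylation by quantile normalization and without control library 1 or PLEK2 library 3, type I interferon without PLEK2 library 1, and fibroblast markers without control library 3. Androgen receptor targets had 0 of 25 members past the threshold over all genes and 3 when adjusted over the list alone, SLC45A3 (0.24) and PMEPA1 (0.16) higher and KLK2 (-0.29, and -0.16 without control library 1) lower (camera adjusted p = 0.60). KLK2 did pass over all genes without control library 3 (-0.39), with no filter, and with the replicate block by limma and by edgeR. The direction of the androgen receptor list by camera was upward while its median was -0.0034 and its mean -0.014. The PI3K-AKT-mTOR components had 0 of 23 past the threshold in either adjustment (camera adjusted p = 0.64), with an upward direction, a median of 0.03 and a mean of -0.03. Of 27 actin cytoskeleton and SRF target genes, RHOB (0.60), a small GTPase that acts on actin, rose, and ZYX (0.22) passed as well when adjusted over the list alone (camera adjusted p = 0.64). In the unfolded protein response and ATF4 list, ATF3 and SESN2 (0.35) rose among 29, and 3 passed when adjusted over the list alone, with SLC7A5 lower (camera adjusted p = 0.34). TNFRSF19 was the 1 of 16 WNT/beta-catenin targets that rose, 2 when adjusted over the list alone (camera adjusted p = 0.20).

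Mesenchymal and EMT genes had 0 of 17 past the threshold and CTGF alone when adjusted over the list alone (camera adjusted p = 0.50). Metalloprotease and invasion genes had 0 of 10 in both counts (camera adjusted p = 0.90), basal and squamous epithelium genes 0 of 11 (camera adjusted p = 0.56) and neuroendocrine genes 0 of 12 (camera adjusted p = 0.75). Prostate luminal epithelium genes had 0 of 20 past the threshold and 2, ELF3 and CLDN3, when adjusted over the list alone (camera adjusted p = 0.34). The type I interferon list had 0 of 26 in both counts (camera adjusted p = 0.082), NF-kB and inflammatory cytokines 0 of 13 (camera adjusted p = 0.34), hypoxia and glycolysis 0 of 27 (camera adjusted p = 0.62) and oxidative phosphorylation 0 of 46 (camera adjusted p = 0.12). Fatty acid synthesis had 0 of 21 and, over the list alone, SCD (0.19) higher (camera adjusted p = 0.13). Of the markers of other cell types, the fibroblast list had 0 of 7 past the threshold and FBLN1 (-0.45) lower when adjusted over the list alone (camera adjusted p = 0.12). The list of leukocyte and red-cell markers had 2 measured members (CD14 and the alpha-globin gene HBA1), and the endothelial list 3 (TIE1, ENG and CLDN5). Both were too short to test, and none of these 5 genes passed. All 37 genes of the mitochondrial chromosome are listed at 0 in every library, so the mitochondrially encoded list was not tested.

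With an estimated correlation in place of the preset one, 0 of the 29 lists passed by camera, where 4 had an unadjusted p under 0.05, and by fry, which does not set a list against other genes, 4 passed. The count of 42 changed genes became 3 without the trended and robust variance of limma, and between 16 and 152 when 1 library was left out (152 without control library 1, 73 without control library 3, and 17, 16 and 17 without PLEK2 libraries 1, 2 and 3), with 16 to 39 of the 42 genes still called, HSPA6 not among them without control library 1 (log2 fold change 5.62) and TNFRSF19 not without control library 3 (0.92) or PLEK2 library 1 (1.04), 2 (0.98) or 3 (1.23).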

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

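All alternatives below were planned before the data were examined, except the removal of the GC and length trend, which was added afterwards. The PLEK2 rise kept its direction and its call in every setting. The count of 42 changed genes (37 higher, 5 lower) became 91 (62 and 29) with no filter, 3 (3 and 0) without trend or robust, 65 by DESeq2 with 11 lower, and 71 (56 and 15) by edgeR with the replicate block. The causes were not tested. Removing the filter adds genes to the test, but the adjusted p of genes tested in both settings changed as well. KLK2, at a log2 fold change of -0.29, had a limma adjusted p of 0.16 with the filter and 0.00051 without it. With limma and the replicate block the count was 77 (57 and 20), 42 of them shared. No pairing by number was seen in values from which the mean of each gene in its group was removed. Correlations of same-numbered libraries were then -0.0016, -0.011 and 0.022. Control libraries 1, 2 and 3 correlated best with PLEK2 libraries 2, 3 and 3. A day or batch shared by number is not excluded by this. The share of calls that were higher was 88.1% in the main test, 68.1% with no filter and 74.0% with the replicate block. Leaving out 1 library gave 16 to 152 changed genes, 16 to 92 higher and 0 to 60 lower: 152 (92 and 60) without control 1, 73 (55 and 18) without control 3, 17 (16 and 1) without PLEK2 library 1, 16 (16 and 0) without PLEK2 library 2 and 17 (16 and 1) without PLEK2 library 3. Of the 42 genes, 16 to 39 stayed called. Of the 13 lists past the threshold, 0 passed with an estimated correlation and 4 by fry. Ribosomal proteins lost their call in 9 of 18 settings, heat shock without control 1 and YAP/TAZ without PLEK2 library 3. List calls were gained 5 times: oxidative phosphorylation by quantile normalization (camera adjusted p = 0.042), without control 1 (0.032) and without PLEK2 library 3 (0.025), type I interferon without PLEK2 library 1 (0.040) and fibroblast markers without control 3 (0.036). The ribosomal median of 0.03 was 0.02 without control 1, 0.06 without control 2, and 0.02, 0.07 and 0.01 without PLEK2 libraries 1, 2 and 3, and the YAP/TAZ median of 0.10 was 0.06 without PLEK2 library 3. Reversed directions, all for genes and lists that had not passed, were gene CCND1 at -0.86 by quantile normalization and lists whose camera direction turned, given by their medians: with no filter, EMT -0.013 and metalloproteases 0.075, at a mean of 50 metalloproteases 0.0065 and neuroendocrine 0.037, and without the GC trend metalloproteases -0.024. Ranges over left-out libraries were -0.0071 to 0.13 for BCL3, -0.14 to 0.17 for HBA1, 0.0098 to 0.034 for PI3K-AKT-mTOR, -0.046 to 0.027 for actin, -0.12 to -0.0015 for EMT, -0.038 to 0.018 for metalloproteases and -3.8e-05 to 0.054 for neuroendocrine genes. At this depth and spread, changes of 0.25 on the log2 scale were recovered for 34% of simulated genes with a mean of at least 50 normalized counts.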

Other observations

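The 9 gene lists of this part were chosen after results were seen, and so were the tests of explanations, apart from the counts of genes and lists over other splits of the libraries. Leaving out each library was planned, and its use as a test of an explanation was chosen afterwards. Genes of the Fanconi and homologous recombination pathways, which repair DNA crosslinks and breaks, lay lower in the PLEK2 libraries. Of 25 members, 22 were below 0, with a median log2 fold change of -0.12 (camera adjusted p = 1.1e-05 over the 9 lists, adjusted p = 0.066 with an estimated correlation). None passed over all genes, and 6 fell when adjusted over the list alone, among them RAD54L (-0.25), FANCA (-0.25) and POLQ (-0.21). Values of some members had been seen before the list was made. Whether this shift is separate from the fall of the G1/S and G2/M lists was not tested. The list was also not tested with a library left out or over other splits of the libraries. NRF2 targets, genes of the antioxidant response, had a median of 0.08 (camera adjusted p = 0.015, adjusted p = 0.37 with an estimated correlation), with FTH1 at 0.31 and HMOX1 at 0.41 and 0 of 21 past the threshold. Lysosome and autophagy genes had a median of 0.06 (camera adjusted p = 0.033, adjusted p = 0.37 with an estimated correlation), with 0 of 27 past it.

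Nuclear copies of mitochondrial genes, a list made after their values were seen, had a median of -0.35 over 15 members (camera adjusted p = 8.3e-05, adjusted p = 0.37 with an estimated correlation), and 1, MTCO2P22, fell, or 3 when adjusted over the list alone. Their summed normalized counts were 53494 in control library 1, 37234 and 38251 in the other control libraries, and 35738, 34284 and 30479 in the PLEK2 libraries. All 37 genes of the mitochondrial chromosome are listed at 0 in every library. Whether reads counted at these copies came from mitochondrial transcripts was not tested, so a fall of the copies themselves is not shown. The lists of metallothioneins (camera adjusted p = 0.076), placental genes (0.67), proteasome subunits (0.83), MHC class I presentation (0.83) and circadian clock genes (0.83) did not pass.

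CSH2 had 31 reads over the control libraries and 10825 over the PLEK2 libraries. A placental gene programme was argued against, though on few expressed genes. The summed normalized counts of the other listed placental genes moved by 0.0033 on the log2 scale, from 297.2 ± 11.1 to 297.9 ± 46.9 (SD, n = 3 per group). Of these 30 genes, only 6 had enough counts to be tested. Among the 6, 4 lay above 0 and 2 below, with a median log2 fold change of 0.26, and none passed. Whole transcripts of the other growth hormone cluster genes counted as CSH2 were argued against too, since those 4 genes held 2 reads over the PLEK2 libraries, although 544 of the 1846 stretches of 50 bases in CSH1 occur in no other cluster gene. A remaining candidate explanation is that reads from the introduced construct were counted as CSH2, as would happen with a growth hormone family sequence in the plasmid. The number of CSH2 reads per 10000 PLEK2 reads was 53.1, 59.9 and 53.7, within 1.13-fold, but PLEK2 itself varied too little between these libraries to decide it, and the plasmid sequence was not used here.

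The rise of the immediate early and p53 lists did not rest on control library 1 alone, since without it both kept their call and at least 0.74 of their median. GC content or gene length bias was argued against as the whole cause, since with that trend removed both lists kept their call and at least 0.94 of their median. Averaged per library, immediate early genes lay 0.42, 0.40 and 0.43 above the control mean in the PLEK2 libraries and at 0.02, -0.04 and 0.02 in the control libraries. A difference between the plasmids or transfections other than PLEK2 cannot be told apart from PLEK2, because 0 further groups, such as another control plasmid or untransfected cells, were compared. A response to the PLEK2 protein therefore stays open as well.

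The mean log2 value of the G1/S and G2/M genes was 11.95 in control library 1, the lowest of the control libraries. Control libraries 2 and 3 had 12.06 and 12.02. Leaving out control library 1 therefore had to enlarge the fall, so its outcome was fixed and is not used as a test. Both lists then kept their call and at least 1.39 times their median. Without control library 2, which had the highest mean of these genes, the medians shrank to -0.058 for G1/S and -0.067 for G2/M, and both kept their call. With the GC content and gene length trend removed both kept their call and at least 0.94 of their median, which argues against GC content or gene length bias as the whole cause. A swing of proliferation genes between libraries stays open: the mean of both lists differed by 0.09 between the groups and by up to 0.08 in another split. The real split was the largest of the 10, and 10 splits are too few for a share under 0.05. Whether slower division, cell density or another difference between dishes was involved was not tested.

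Over the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave 42 changed genes, and the highest other gave 0 by limma and 0 by edgeR, with 687 to 1058 genes at an unadjusted p under 0.05 in the others against 1893 in the real one. It also gave 13 lists past the threshold, and the highest other gave 6. With 10 splits no share can lie under 0.05.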
